A study of Homo sapiens with 6 samples.

How the data were processed

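Total RNA from 6 samples, 3 of the S116A and 3 of the S116D line, was labelled with biotin and hybridised to Affymetrix HG-U133 Plus arrays, per the labels' protocols. The deposited table held 1 value per probe set and array, 54675 probe sets in all. The submitters' processing notes name MAS5 and RMA, without saying what each was used for. Versions, background correction and filters are not given in the sources used here. The deposited values were taken as log2 signals because all lay between 4.336 and 15.33 and the quartiles of the 6 arrays nearly coincided, as in multi-array summaries. Such summaries compress differences of dim probe sets, and no detection calls were part of the table, so no probe set was called absent. The planned pseudocounts for linear values were not needed. Precision was limited by the number of arrays, 3 per line.

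Control probe sets (62) were left out, leaving 54613. GEO's platform annotation, with symbols taken through the gene identifier from RefSeq (assembly GRCh38.p14), gave 1 gene for 41091 probe sets and several for 1801, and 11721 probe sets are unnamed here. Of the 41091, 41037 had their gene identifier in the RefSeq table. Only probe sets with 1 gene were named. Each of the 19775 genes was represented by its probe set with the highest mean over all 6 arrays. Of 10523 genes with over 1 probe set, 14 had probe sets called in both directions.

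Groups were taken from sample titles. The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) are limma's moderated ones, SDs are over the 3 arrays of a line, and fold differences are 2 to the power of the log2 difference. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none is reported for single genes. The 33 gene lists held 794 genes, of which 733 were measured, and were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry, adjusted over the 33 lists. Lists share genes, and sizes of lists refer to measured genes. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took PEA15 and CTNNB1, the 15 largest rises and 15 largest falls among called genes whose lines did not overlap and whose higher mean exceeded the median signal of 7.882, up to 4 called members of each list with the smallest adjusted p, and up to 2 members of lists with no call. Genes named beyond the rule, to make up counts of 5 or fewer or where marked, were chosen after their values were seen.

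The fit was tested on simulated data with the means and residual spread of these 19775 genes, with 200 genes changed. It recovered 59.7% of changes of 0.5, 97.0% of changes of 1 and 100% of changes of 2 on the log2 scale, and 6.63% of its calls were false. A shift of 0.5 added to the interferon-stimulated list was recovered by camera, and 0 lists that shared no gene with it were called. Genes were drawn independently of each other in this simulation. It therefore cannot test the preset correlation of camera, and its share of false calls need not hold for correlated genes.

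The replicate numbers were not taken as pairs, a choice fixed beforehand because the labels name no covariate. Same-numbered arrays of the lines did not all deviate together from their group means. Alternatives were quantile normalization, median centring, a filter on dim probe sets, eBayes without trend, the replicate number as a block, array weights, 2 other rules for the probe set of a gene, ordinary t statistics for the gene count alone, an estimated correlation in camera, and leaving out each array. The test of cross-hybridisation among protocadherins was redefined after its values were seen. It first took the other genes of their run, which the shift itself bounds, then the 10 nearest other genes on each side, and last 4 widths of 5 to 20 genes per side, all of which had to pass. Gene order along chromosomes, used for neighbouring genes, came from the same RefSeq table, whose coordinates are not printed because the build behind the array annotation is not given.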

Results

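Gene expression was measured on 6 Affymetrix HG-U133 Plus arrays, in 2 stably transfected derivatives of SKOV3.ip1, an intraperitoneally passaged subline of the human ovarian carcinoma line SKOV3. PEA-15 is a small death-effector-domain protein that binds ERK and FADD and whose binding is set by serine phosphorylation. The S116A line carried a form with alanine in place of a serine, which cannot be phosphorylated there. The S116D line carried a phosphomimetic form with aspartic acid instead. The labels do not settle whether the S116D form holds 1 or 2 substitutions, since its titles name 1 serine, its sample characteristics name another as well, and the treatment text numbers the residue differently. Each line was represented by 3 arrays. The labels do not say whether these came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. No parental or empty-vector array was analysed here, so each difference is between the 2 lines and is given as S116D minus S116A on the log2 scale.

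The 6 arrays were closely scaled, with median log2 signals between 7.862 and 7.893 over 54613 non-control probe sets. Arrays of one line correlated at r between 0.9951 and 0.9979 across all probe sets, and arrays of different lines at r between 0.9866 and 0.9902. The first principal component held 67.5% of the variance between arrays and separated the lines. The log2 ratio of the 3′ to the 5′ control probe set, a sign of RNA integrity, ranged from 2.27 to 2.474 for ACTB and from 0.6526 to 0.7932 for GAPDH, and the ranges of the lines overlapped for both. A second component, with 19.9% of the variance, set S116A 1, S116A 2 and S116D 1 apart from S116A 3, S116D 2 and S116D 3. These sets correspond to no label. The GAPDH ratio separated them, at 0.726 to 0.7932 against 0.6526 to 0.7083, as did the 3′ ACTB signal (at least 14.92 against at most 14.83) and the array medians (7.862 to 7.885 against 7.888 to 7.893), whereas the ACTB ratio did not. All 2407 genes called below had the same direction within each set, against 67.1% of all genes. The called genes were chosen on the same arrays, and each set holds arrays of both lines. A gene whose lines do not overlap must then have the same direction in both sets, so this share is no separate evidence. Most S116A arrays fell in the first set and most S116D arrays in the second, so differences given without a block carry part of any set difference. With the sets as a block, chosen after seeing the data, 4411 genes were called. Genes differing at least 2-fold then numbered 350, 212 higher and 138 lower, of which 310 were shared with the main fit. Lists past camera were 3 higher and 4 lower with the block, against 2 higher and 9 lower without it.

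The first question was whether the transfected gene and the gene for β-catenin differed in transcript level. CTNNB1, which encodes β-catenin, was higher in the S116D line on its brightest probe set, at 13.35 ± 0.12 against 12.85 ± 0.10 (SD, n = 3 each), a 1.41-fold difference with a limma adjusted p over all probe sets of 0.0087. A second CTNNB1 probe set rose by 1.08 (95% interval 0.803 to 1.35), and the third, at 6.77 in the S116A line and below the median signal, differed by 0.10 (95% interval -0.0815 to 0.272). PEA15 did not pass the threshold on either of its probe sets. Its brighter probe set read 12.61 ± 0.10 in S116A and 12.55 ± 0.12 in S116D (SD, n = 3 each), a difference of -0.06 with a 95% interval from -0.26 to 0.139 and a limma adjusted p of 0.82. Its second probe set differed by -0.19 (limma adjusted p = 0.20, unadjusted 0.035, interval -0.36 to -0.0172). There the lines did not overlap, at 10.96 to 11.03 in S116A and 10.74 to 10.87 in S116D. Probe positions were not used here, and probe sets of this array type lie near transcript ends, so these values may not read the vector transcript.

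Across the 19775 genes with a probe set of their own, 2407 (12.2%) differed between the lines at a limma adjusted p under 0.05, 1342 of them higher and 1065 lower in S116D. At least 2-fold differences were called for 334 genes, 184 higher and 150 lower, and at least 4-fold differences for 71. The values of the lines did not overlap for 5503 genes (27.8%), where chance gives 10% for 3 arrays against 3. On probe sets, 4672 of 54613 were called. The gene count was 1447 without S116A 1, 1560 without S116A 2, 1451 without S116D 2 and 1528 without S116D 3, and 948 with ordinary t statistics, which borrow no information between genes.

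Of the genes named by the rule, 20 lost their call when 1 of the arrays was left out, at limma adjusted p between 0.051 and 0.16. Without S116A 1 these were CCND1, BID, GABARAPL2, MCM5, MCM10, GINS2, CDC25C, IL6, C3, GSR, FBLN1 and MAP2. Without S116A 2, UVRAG, LIF, NDRG1, ENO2, UQCRC1 and GADD45A were lost beside CCND1, MCM10, CDC25C, IL6, C3 and MAP2. Without S116D 2 the 12 losses were all among these genes, without S116D 3 MMP10 and TP53I3 were lost beside 9 of them, and without S116A 3 or S116D 1 the losses were C3, UQCRC1, GINS2 and LIF. On the median of a gene's probe sets, 13 named genes were no longer called (limma adjusted p 0.064 to 0.96): TPM2, ESR1, SORBS2, CD44, FAS, MCM10, GINS2, CDC25C, IFIH1, TGFB2, IGF1R, NRG1 and FOLR1. With probe sets of the unshared type preferred, KRT7 (-0.18) and TAGLN (0.08) were lost too. Of 73 called genes named by the rule that have over 1 probe set, 41 were called on fewer than all of them and 27 on at most 1 in 2. Those 27 were ZC3HAV1L, TPM2, EHF, ESR1, LRRC17, SORBS2, CDH1, CD44, SFRP1, GSK3B, TNFRSF10D, MCM10, KRT19, KRT7, ITGB8, ITGB5, NRP2, IFIH1, SC5D, TRIB3, TXNRD1, TGFB2, IGF1R, NRG1, GATA6, FOLR1 and MAP2.

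The largest rises were those of MRLN and ZC3HAV1L, which differed from each other by less than their standard errors and started from signals below the median. MRLN, a micropeptide regulator of the muscle calcium pump, rose from 7.56 ± 0.74 to 11.90 ± 0.28 (SD, n = 3 each), a 20.3-fold difference. ZC3HAV1L rose 19.8-fold on 1 of its 2 probe sets, the kinase gene ALPK2 13.6-fold, RHOBTB1 11.4-fold and the cell-surface proteoglycan GPC6 9.68-fold. SPANXB1, a cancer-testis gene whose near-identical copies can share its probes, rose 9.37-fold. PSMB9, a subunit of the immunoproteasome, rose from 8.51 ± 0.48 to 11.47 ± 0.31, or 7.78-fold, and BST2, the interferon-induced tetherin, from 8.67 ± 0.37 to 11.59 ± 0.12, or 7.55-fold. LDOC1, TRIM6, TMEM47, VAV3, UCP2, a mitochondrial carrier, NEXMIF and TPM2, a tropomyosin, completed the 15 largest rises, at 5.70-fold to 8.34-fold. TPM2 rested on 2 of its 4 probe sets.

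The largest falls were those of BCAT1 and DAW1, which differed from each other by less than their standard errors. BCAT1, the cytosolic branched-chain aminotransferase, fell from 11.76 ± 0.25 in S116A to 7.01 ± 0.31 in S116D (SD, n = 3 each), a 26.9-fold difference, and DAW1 fell 26.0-fold. CTH, which makes cysteine from cystathionine, fell 17.3-fold, from 12.79 ± 0.14 to 8.67 ± 0.07. The gap junction gene GJA1, which encodes a connexin, fell 15.3-fold, the epithelial transcription factor EHF 11.8-fold and PTPRR, a phosphatase acting on MAP kinases, 11.6-fold. The estrogen receptor gene ESR1 fell 10.2-fold on the probe set with the highest signal, the only one of its 9 that was called. CDH1, which encodes E-cadherin, fell 6.99-fold, from 8.87 ± 0.68 to 6.06 ± 0.18, on 1 of 2 probe sets. COX7B2, LRRC17, TSPYL5, SORBS2, NPFFR2, TRIB2 and PRSS12 fell between 6.78-fold and 8.91-fold. In S116D, DAW1 (6.50), EHF (5.87) and CDH1 (6.06) lay below the lower quartile of every array, which was 6.623 to 6.653. Signal over background could not be judged, so folds that start or end at dim signals, and ranks among them, are not exact. Limma adjusted p-values of the 30 genes with the largest changes ran from 1.0e-06 to 6.2e-04.

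**Figure D1:**
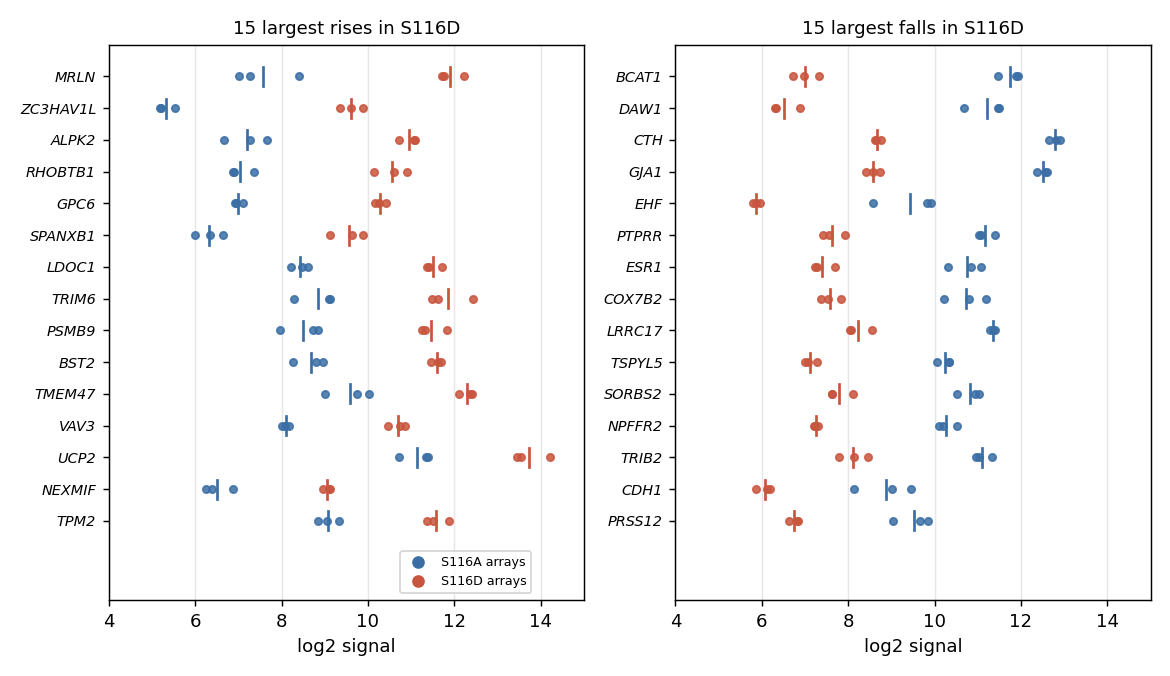
Log2 signal (x axis) of the 15 genes with the largest rises (left) and falls (right) in S116D. Points are single arrays, 3 per line, and vertical ticks are the means of each line. The lines do not overlap for any gene shown, and MRLN and BCAT1 change by 20.3-fold and 26.9-fold.

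Gene lists fixed beforehand addressed which processes moved together. Of the 33 lists, 11 passed limma's camera test with a preset correlation between genes of 0.01 (Benjamini-Hochberg adjusted p under 0.05), 2 higher and 9 lower in S116D. With an estimated correlation none of the 11 passed, at adjusted p between 0.194 and 0.684, and 1 of the 33 lists had an unadjusted p under 0.05, so calls of whole lists rest on the preset value. By fry, which asks only whether the genes of a list move one way, 8 lists passed. Of the 11 lists past camera, 5 did not pass fry: ERK-responsive genes (fry adjusted p = 0.071), integrins and focal adhesion (0.072), epithelial genes (0.13), S-phase genes (0.21) and hypoxia and glycolysis (0.26).

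Antigen presentation was the list with the most rises. Of 22 measured members 12 were higher in S116D and none lower, also 12 when adjusted over the list alone (camera adjusted p = 4.1e-06, adjusted p = 0.61 with an estimated correlation). Besides PSMB9, HLA-B rose by 1.61 ± 0.20 (SE), HLA-C by 1.14 ± 0.14 and the peptide transporter gene TAP1 by 1.27 ± 0.16, all with limma adjusted p near 0.0017 or below. PSMB8, another immunoproteasome subunit (1.90), and NLRC5, a transactivator of class I genes (1.11), also rose and were chosen after their values were seen. Of the class II pathway, HLA-DRA (-0.02), CD74 (0.01) and CIITA (-0.09), also chosen afterwards, did not pass. Probe sets of HLA genes can read several class I genes, so HLA-B and HLA-C are not independent readings. The median difference of the list was 0.400, against 0.202 with unshared probe sets preferred and 0.587 on the median of a gene's probe sets.

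Interferon-stimulated genes were higher in part. Of 30 measured members 10 rose, SAMD9 alone fell (-0.94), and 19 did not pass. Adjusted over the list alone the counts were 12 and 1 (camera adjusted p = 1.4e-05, adjusted p = 0.54 with an estimated correlation). BST2 rose most, with smaller rises of IFI35 (1.37 ± 0.12, SE), IFIH1, an RNA sensor (1.15 ± 0.12, on 1 of its 3 probe sets and from a low signal of 5.79), and USP18, which removes ISG15 from proteins (1.99-fold). MX1 (0.24, limma adjusted p = 0.081), IFIT1 (0.42, 0.33) and OAS1 (0.11, 0.51), chosen afterwards as widely used members, did not pass. Leukocyte markers did not move with these lists, since none of 17 was called by limma or reached an unadjusted p under 0.05 (0 of 17), and PTPRC differed by 0.11 ± 0.07 (SE). NF-κB and cytokine genes gave 2 higher (IL6 by 0.56, C3 by 0.56) and 2 lower (CCL20 by -0.59, LIF by -0.62) of 27, with the same counts adjusted over the list alone, and no call for the list (camera adjusted p = 0.57).

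**Figure D2:**
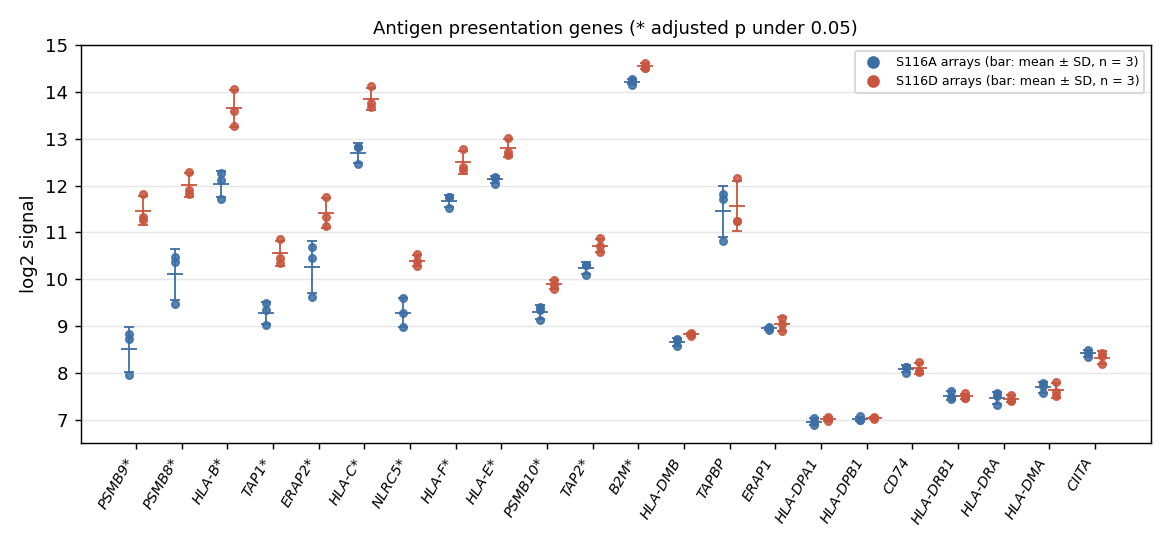
Log2 signal (y axis) of the 22 measured antigen presentation genes, ordered by the difference between lines. Points are arrays, bars are mean ± SD (n = 3), and asterisks mark limma adjusted p under 0.05. The 12 marked genes are higher in S116D, and for the class II genes at the right, such as HLA-DRA and CD74, the lines lie close together.

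Called adhesion genes were mostly lower in S116D. Of 26 integrin and focal adhesion genes 6 fell, THBS1 alone rose (0.66), and 19 did not pass; adjusted over the list alone, 7 fell and 1 rose (camera adjusted p = 0.0030, adjusted p = 0.67 with an estimated correlation). ITGA6, the integrin α6 gene, fell from 11.92 ± 0.06 to 9.55 ± 0.26 (SD, n = 3 each), 5.18-fold. LAMB3, a laminin-332 chain, fell 4.46-fold, ITGB8 2.12-fold and ITGB5 1.35-fold. YAP/TEAD target genes had 7 of 22 members lower and none higher, 10 adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.19 with an estimated correlation). NT5E, the ecto-nucleotidase CD73, fell 4.33-fold, AXL, a receptor tyrosine kinase, 1.52-fold, F3, tissue factor, 1.60-fold, and TGFB2 1.44-fold, the last on 1 of its 5 probe sets. The classical targets CCN1 (-0.35, limma adjusted p = 0.19) and CCN2 (-0.73, 0.22), chosen afterwards, did not pass.

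Epithelial and mesenchymal genes both included more falls than rises. Of 29 epithelial genes 8 fell, DSC2 alone rose and 20 did not pass, with 11 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.67 with an estimated correlation). The keratin genes KRT19 and KRT7 fell 4.80-fold and 2.96-fold and KRT18 1.62-fold, beside CDH1. KRT7 was called on 2 of its 4 probe sets. Of 29 mesenchymal genes 10 fell and 4 rose, with 12 and 6 adjusted over the list alone. That list did not pass camera (adjusted p = 0.17) but passed fry downwards (adjusted p = 0.030). Its median difference was -0.003 against a mean of -0.15, so the fry call does not describe a typical member. FBN1, fibrillin-1, fell 4.68-fold, TGFBI 2.94-fold, CDH2, which encodes N-cadherin, 2.20-fold and AXL 1.52-fold. Vimentin (VIM) differed by 0.10 (limma adjusted p = 0.41) and was chosen afterwards. The 4 rises were ZEB1, a repressor of CDH1 (0.86), SPARC (1.13), TAGLN (1.13) and FN1 (0.55). TGF-β response genes were split, 3 higher and 4 lower of 27 (4 and 4 adjusted over the list alone, camera adjusted p = 0.61), with TAGLN, ID2 (0.97) and TPM1 (0.35) higher and TGFBI, TGFBR3 (-0.62), TGFB2 and LTBP1 (-0.53) lower. Of 15 fibroblast markers S100A4 (-1.37) and MFAP5 (-1.10) fell and FBLN1 rose (0.93), with 3 lower and 1 higher adjusted over the list alone and camera adjusted p = 0.61; their median was 0.01 and their mean -0.11.

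Targets of the Wnt/β-catenin pathway gave 5 falls and no rise among 25 measured genes, 6 falls adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.54 with an estimated correlation). DKK1, itself a secreted Wnt antagonist, fell from 13.45 ± 0.06 to 12.01 ± 0.10 (SD, n = 3 each), 2.72-fold, and BMP4, a morphogen, fell 2.56-fold. CD44, an adhesion receptor, fell 1.41-fold on 1 of its 13 probe sets, though the median of its probe sets differed by 0.022 in the other direction and was not called, and CCND1, cyclin D1, fell 1.44-fold. MYC was the remaining fall (-0.78). AXIN2 (-0.11, limma adjusted p = 0.62) and LEF1 (0.23, 0.16) did not pass; these 3 were chosen afterwards. Among 28 pathway components 4 rose and 3 fell, with 5 and 3 adjusted over the list alone and no call for the list (camera adjusted p = 0.84, with a mean of 0.05 against a median of -0.03). WNT5A rose 4.92-fold, from 9.02 ± 0.25 to 11.32 ± 0.62, with WNT7A (0.69), FZD1 (0.45) and CTNNB1 also higher, while SFRP1, GSK3B and DVL1 fell 1.54-fold, 1.43-fold and 1.46-fold.

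ERK-responsive genes, of interest because PEA-15 binds ERK, had 8 falls and 2 rises among 29, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.67 with an estimated correlation). The ERK phosphatase gene DUSP4 fell 3.09-fold on its brightest probe set, 2.71-fold on another and about 15-fold on the third, where S116D read only 5.97 and the fold is not exact. EMP1 fell 2.65-fold and the receptor gene EPHA2 1.71-fold, whereas SPRED1, an inhibitor of this pathway, rose 1.41-fold, as did HBEGF, a growth factor (0.49). DUSP6 (0.13, limma adjusted p = 0.36) and SPRY4 (0.07, 0.71), chosen afterwards, did not pass. CCND1 and MYC belong to this list and to the Wnt targets. The call for this list, like that for epithelial genes, ended without S116A 2 (camera adjusted p = 0.29 and 0.14) and, for both, among probe sets above the median signal and with the 2 sets of arrays as a block, at up to 0.056.

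Death receptor genes were included because PEA-15 acts on that pathway. Of 17, FAS (-0.84 ± 0.09, SE) and the decoy receptor gene TNFRSF10D (-1.30 ± 0.15) fell and BID rose (0.51 ± 0.10), against 3 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.91, median 0.08 and mean -0.04). FADD (0.31), CASP8 (0.31) and CFLAR (0.29), chosen afterwards, had limma adjusted p of 0.071, 0.093 and 0.17. In the BCL2 family and inhibitors of apoptosis, BMF alone rose of 18 (0.51 ± 0.08; also 1 adjusted over the list alone, camera adjusted p = 0.57). Of 26 autophagy genes ATG12 (-1.22 ± 0.07), MAP1LC3B (-1.04 ± 0.12) and GABARAPL2 (-0.35 ± 0.07) fell and UVRAG rose (0.40 ± 0.08), with 6 lower and 5 higher adjusted over the list alone (camera adjusted p = 0.47). Among p53 targets 3 rose, XPC (0.49), CCNG1 (0.42) and TP53I3 (0.36), and 3 fell, FAS, GADD45A (-1.21) and DDB2 (-0.42), of 21, with 3 and 5 adjusted over the list alone and camera adjusted p = 0.61 (median 0.01, mean -0.09).

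Of the cell cycle lists, 6 of 29 S-phase genes fell and MCM10 rose (0.57, on 1 of 3 probe sets), with 8 and 1 adjusted over the list alone (camera adjusted p = 0.0066, adjusted p = 0.68 with an estimated correlation). MCM4 fell 1.38-fold, MCM5 1.32-fold and GINS2 1.64-fold, and the call for GINS2 was lost on the median of its probe sets (-0.01). Of 30 mitotic genes 5 rose and none fell, also 5 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.067). BUB1B, KIF20A and HMMR rose 1.49-fold, 1.49-fold and 1.51-fold, and CDC25C rose 1.37-fold and PTTG1 by 0.37. SPRED1, THBS1, BMF and BUB1B lie within 1 run of 66 neighbouring genes of which 30 were called higher and 0 lower in S116D, and GINS2 and COX4I1 within 1 run of 33 with 14 lower and 0 higher.

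Hypoxia and glycolysis genes had 3 falls and 2 rises of 29 (5 and 4 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.67 with an estimated correlation), and the list call ended without S116A 1 or S116D 2 (highest adjusted p = 0.13), among probe sets above the median signal and with the 2 sets of arrays as a block (0.13 at most). HK2, hexokinase 2, fell 2.75-fold, NDRG1 1.92-fold and PGAM1 by 0.29, while PFKFB3 and ENO2 rose 1.47-fold and 1.60-fold. The unfolded protein and amino acid stress list had 5 falls and 3 rises of 30 (9 and 6 adjusted over the list alone, camera adjusted p = 0.32, fry adjusted p = 0.0038 downwards). Its median difference was -0.02 against a mean of -0.18, with CTH at -4.12, so the fry call does not describe a typical member. Beside CTH, the amino acid transporter SLC7A5 fell 2.17-fold, and STC2 (-0.51), DNAJC3 (-0.40) and SHMT2 (-0.26) were lower, while VLDLR, TRIB3 and DNAJB9 rose 2.02-fold, 1.37-fold and by 0.44. In oxidative phosphorylation COX4I1 fell (-0.49) and UQCRC1 rose (0.32) of 25, 1 and 1 adjusted over the list alone (camera adjusted p = 0.29). Of 17 cholesterol synthesis genes SC5D alone rose (1.05), also 1 adjusted over the list alone (camera adjusted p = 0.61). Of 21 NRF2 targets TXNRD1 fell (-0.70) and GSR rose (0.61), the same adjusted over the list alone (camera adjusted p = 0.61). None of 20 ribosomal protein genes was called by limma on its brightest probe set (2 at an unadjusted p under 0.05), RPL22 (-0.15) and RPS14 (0.26) having the smallest p, and camera adjusted p was 0.61. Dimmer probe sets of 3 of them were called lower, 2 of 5 for RPL22 (-0.44 and -0.34), 2 of 4 for RPL37 (-1.53 and -0.81) and 1 of 2 for RPS23 (-0.35).

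Markers of ovarian carcinoma and the Müllerian lineage had 3 falls and 1 rise of 19, the same adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.67 with an estimated correlation). GATA6 fell from 11.49 ± 0.18 to 8.85 ± 0.03 (SD, n = 3 each), 6.25-fold on 1 of its 2 probe sets, and SOX17 1.52-fold, while FOLR1, the folate receptor, rose 1.64-fold on 1 of 2 probe sets and was -0.20 on the other. ESR1 was the third fall. Genes used as stem cell markers had 5 falls and no rise of 18, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.54 with an estimated correlation). The drug efflux gene ABCG2 fell 4.06-fold and ALDH1A3, an aldehyde dehydrogenase, 4.76-fold, beside ITGA6, CD44 and KLF4 (-0.65). The call for the stem cell list ended without S116A 1 (camera adjusted p = 0.072) and under 4 of 9 other settings, up to 0.12. That for the ovarian list ended without S116A 1, S116A 2, S116D 2 or S116D 3 (camera adjusted p up to 0.13) and under 5 of 9 other settings, up to 0.17.

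Receptor tyrosine kinase genes and their ligands had 5 falls and 1 rise of 27, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.070). MET, the hepatocyte growth factor receptor, fell 1.49-fold, with 3 of its 4 probe sets called lower, and IGF1R 1.51-fold on 1 of 5 (0.029 on the median of its probe sets, not called), INSR (-0.48), TGFA (-0.32) and AXL were lower, and NRG1 rose 1.71-fold on 1 of 6. Extracellular protease genes split 3 to 3 of 32, the same adjusted over the list alone (camera adjusted p = 0.86, mean 0.07 and median -0.02). MMP1, interstitial collagenase, rose 4.72-fold from 9.73 ± 0.10 to 11.96 ± 0.27 (SD, n = 3 each), MMP10 rose 2.04-fold and TIMP1 by 0.59, while ADAMTS1 fell 1.95-fold and TIMP2 (-0.48) and ADAM9 (-0.22) were lower. Of 27 angiogenesis factors 4 fell and 2 rose, 5 and 3 adjusted over the list alone (camera adjusted p = 0.11), with VEGFC lower 2.69-fold, EDN1 1.68-fold and NRP2 1.63-fold beside EPHA2, and NRP1 (0.85) and THBS1 higher. The other lists of foreign cell types gave KDR alone of 15 endothelial markers (-0.43, at 6.15 in S116A; also 1 adjusted over the list alone, camera adjusted p = 0.30), none of 13 hepatocyte and kidney markers by limma on the brightest probe set, with 0 at an unadjusted p under 0.05 (SERPINA1 0.13, though 2 of its 4 probe sets were called higher, by 0.31 and 0.23; AFP -0.08, camera adjusted p = 0.84, median 0.0031 and mean -0.0047), and MAP2 alone of 15 neuronal markers (-1.63 with overlapping lines, none adjusted over the list alone, limma adjusted p = 0.051 without trend, camera adjusted p = 0.32).

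**Figure D3:**
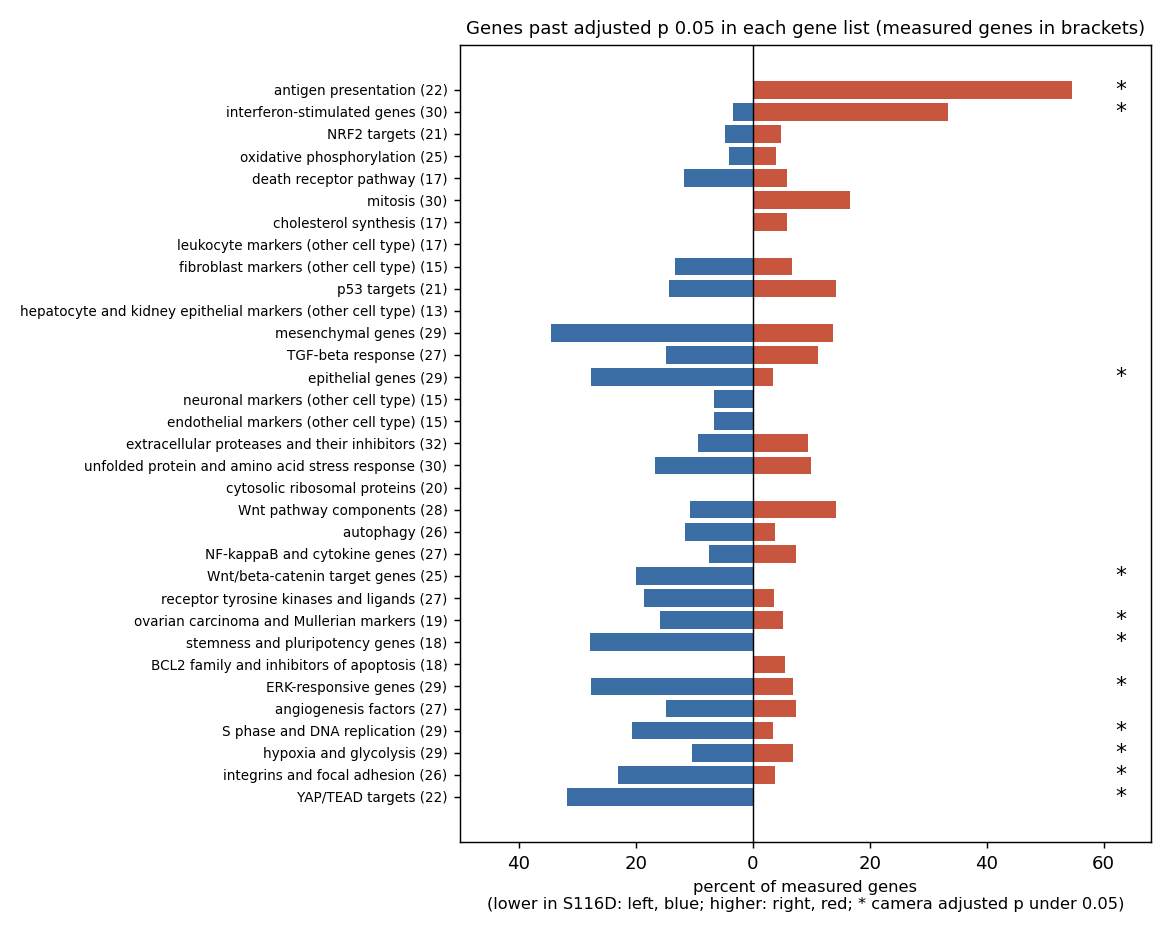
Percent of the measured genes of each list (x axis) called lower (left, blue) or higher (right, red) in S116D at limma adjusted p under 0.05. Lists are ordered by median log2 difference, with the number of measured genes in brackets, and asterisks mark the 11 lists past camera with the preset correlation. Antigen presentation, with 12 of 22 genes higher, stands at the top, and YAP/TEAD targets, with 7 of 22 lower, at the bottom.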

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

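The fit with the 2 sets of arrays that deviate together as a block was chosen after seeing the data; the other settings were planned. The count of 2407 genes rose to 3892 with the replicate block, 3681 with array weights and 4411 with the block of the 2 sets, and fell to 948 with ordinary t statistics, of which 890 were shared. The 3 larger lists held 2405, 2405 and 2406 of the 2407 genes. Probe sets numbered 7340 with the replicate block and 8099 with the 2 sets, against 4672. Leaving out 1 array gave 1447 to 2593 genes, 2608 to 4674 probe sets, 321 to 354 genes differing at least 2-fold and 8 to 13 lists. The gene count fell by over 1.5 times without S116A 1 (1447), S116A 2 (1560), S116D 2 (1451) or S116D 3 (1528), and was 2492 without S116A 3 and 2593 without S116D 1; the reason was not tested. Genes differing at least 2-fold stayed between 241 and 350 in the other settings, and PEA15 was not called in any, ordinary t statistics having been run for the gene count alone. Named genes lost 13 calls on the median of their probe sets, 9 with unshared probe sets preferred, 1 (MAP2, adjusted p = 0.051) without trend, and 2 to 12 without single arrays. Lists past camera numbered 0 with an estimated correlation, 7 among probe sets above the median signal and 7 with the block of the 2 sets, against 11. Of the 11, Wnt/β-catenin targets, S-phase genes, integrins, interferon-stimulated genes, antigen presentation and YAP/TEAD targets kept their calls in all settings other than the estimated correlation. The same-numbered arrays' deviations correlated at 0.528, -0.105 and 0.547, and S116A 2 correlated best with S116D 1. These values are mixed, and the numbers were not taken as pairs because the labels name no covariate. CD44 and IGF1R turned to 0.022 and 0.029 on the median of their probe sets and FOLR1 to -0.20 on its probe set of the single-gene type, none of these called; the cause was not tested. The pseudocounts planned for linear values were not run because the table holds log2 values. Signal over background could not be judged, since the table has no detection calls.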

Other observations

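The tests of gene families and of runs of neighbouring genes were chosen after results had been seen; the tests of other splits, of neighbours of 2-fold genes, of leukocytes and of scaling were written beforehand. Among 325 families of at least 8 genes sharing the start of their symbol, 3 passed camera with the preset correlation. Of 17 genes of the protocadherin β cluster (PCDHB), which encode neuronal-type adhesion proteins, 14 were higher in S116D and none lower, with a median of 0.734 (camera adjusted p = 6.4e-13, adjusted p = 0.99 with an estimated correlation). PCDHB5 rose by 1.87 ± 0.12 (SE), PCDHB7 by 2.08 ± 0.13 and PCDHB14 by 2.47 ± 0.29. Of 9 pregnancy-specific glycoprotein genes (PSG) 8 were higher, with PSG3 by 1.05 ± 0.10 and PSG5 by 1.03 ± 0.15 (camera adjusted p = 4.2e-05, adjusted p = 0.99 with an estimated correlation). The 8 genes named IFI had 7 higher (camera adjusted p = 2.0e-05, adjusted p = 0.99 with an estimated correlation), and overlap the interferon-stimulated list. Members of the PCDHB and PSG families are similar in sequence and can share probes, so their number of calls can overstate the number of independent readings. Under quantile normalization and median centring no member of these families was called lower and 7 to 14 were called higher.

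The first pattern was the extent of the difference between the lines. The real split of the 6 arrays gave 2407 genes, as many as 1 of the 10 splits of 3 against 3, itself. The highest other was 56, for the split along the 2 sets of arrays that deviate together, and 10 splits are too few for a share under 0.05. Copy number segments as the main source of genes differing at least 2-fold stay undecided. Of the 334 such genes, 8.08% (27, exact 95% interval 5.39% to 11.5%) had 10 neighbours with a median of at least 0.2 in the same direction. Gene orders shuffled within chromosomes gave at most 8 genes. The share lay below the one predicted for copy number, but neighbours were taken whatever their signal, and dim ones can hide a shift. In the run from NECAB2 to FLJ30679, described below, the median was -0.125 over all genes. Over its genes above the median signal it was -0.623. Each construct is represented by 1 stable line, so an effect of the substitution in PEA-15 and any other difference between the lines, such as clonal selection or the level of the transgene, stay open and were not tested.

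The second pattern was that neighbouring genes shifted together, with a Spearman rho across genes of 0.185 between a gene and the median of its 10 neighbours (highest of 100 shuffled orders 0.0799; genes are not independent replicates). In 3 runs, which held 64 of the 2407 called genes, the median over 21 genes exceeded the highest of the shuffled orders, 0.459. From LINC02352 to ZFYVE19 30 of 66 genes were called higher, from ANKHD1 to PCDHGB7 20 of 46 were called higher, and from NECAB2 to FLJ30679 14 of 33 were called lower, with 0 in the other direction in each. The PCDHB cluster lies within the run from ANKHD1 to PCDHGB7, so its family call and this run are not separate observations. A copy number difference of these runs is a candidate explanation, as is regional regulation. They cannot be told apart, and no DNA was measured. Among genes above the median signal, the shifts spread 2.36, 2.17 and 3.19 times as widely in the runs as elsewhere. Bootstrap 95% intervals were 1.46 to 2.81, 1.41 to 3.55 and 0.997 to 4.6. Runs were extended while the 21-gene median stayed at 0.2 or more in their direction, so less shifted genes at their ends can widen the spread. Cross-hybridisation among protocadherins stays open for the second run, where 15 of 32 protocadherins and 5 of 14 other genes were called higher: of the nearest other genes above the median signal, 75% with 10 genes per side were higher by at least 0.1 (exact 95% interval 50.9% to 91.3%), but 60%, 63.3% and 60% with 5, 15 and 20 per side had intervals from 26.2%, 43.9% and 43.3%, below the 50% set as the bar, and elsewhere the share was 27.8%.

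The third pattern was that part of the interferon-stimulated (10 of 30) and antigen presentation (12 of 22) genes were higher in S116D, while 19 and 10 did not pass and neither list passed camera with an estimated correlation (adjusted p = 0.54 and 0.61). Leukocytes among the S116D cells are argued against, because 0% of the 17 measured leukocyte markers were called higher, with LCP1 at -0.04 ± 0.07 (SE) and CD52 at -0.05 ± 0.07. A difference in overall scale left in the deposited values was small, the array medians lying between 7.862 and 7.893. Quantile normalization and median centring therefore had little to change, and the median of the interferon-stimulated list moved by at most 7.62%. That outcome was largely fixed by the close scaling, so no further conclusion on scaling is drawn from it. The antigen presentation median was 0.400 as deposited, 0.426 with quantile normalization and 0.388 with median centring. The arrays were already closely scaled when deposited, so these settings cannot test the submitters' own normalization. The rule for the probe set of a gene moved the antigen presentation median more. It was 0.202 with unshared probe sets preferred and 0.587 on the median of a gene's probe sets. An effect of the PEA-15 form and a difference between lines unrelated to it, for example in their response to the introduced vector, remain open, since the design holds 1 line per form.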
